A study of Homo sapiens with 9 samples.

How the data were processed

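The series holds 9 libraries of total RNA from JJN3 cells, depleted of ribosomal RNA and sequenced on an Illumina platform: 3 untreated, 3 exposed to DC-1-170 and 3 to DC-1-192, each at 30 nM for 4 h. Per the labels' protocols the RNA had an integrity number over 8. The authors deposited 1 file per library, with a read count and an RPKM value for each RefSeq transcript and its hg19 coordinates, per the file headers. Per the submitters' processing notes, Trimmomatic, BWA and the genome build hg19 were used, without versions. The program that counted reads, its annotation release and its use of strand are not given in the sources used here. In transcripts with high counts, the ratio of deposited count to RPKM differed between libraries by 1 factor per library, within 0.333%. Agreement with transcript length was not checked, and the counts were the values tested. A read in an overlap of genes, or shared by near-identical copies, may have been counted for either. Of the genes named, ARHGEF3, BZRAP1, CCNE2, FAM83E, FAN1, GAS5, IDI1, KIF20A, MAP3K14, PITPNM2, PSMD1, SLC2A1, SLC7A11, SNHG12 and SNHG3 overlap another gene of the deposited annotation, small RNAs aside, and their values are uncertain to that extent.

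The files held 41937 transcript rows, of which 11 were missing from 1 library and left out, leaving 23360 genes. Of 5258 genes with several transcripts over a mean count of 10, 694 (13.2%) had transcripts with identical counts in all 9 libraries, so reads had been counted once per transcript. By a rule fixed for that case the transcript with the highest mean count stood for its gene, and sums over transcripts were an alternative. Gene counts came to 15.5 M, 20.2 M and 17.2 M in the untreated libraries, 13.4 M, 17.8 M and 14.4 M after DC-1-170, and 17.7 M, 12.6 M and 13.2 M after DC-1-192. RN45S took 11.8%, 15.1% and 11.3% of these in untreated, 16.8%, 34.1% and 57.1% in DC-1-170 and 52.5%, 26.9% and 47.6% in DC-1-192 libraries. All replicate pairs differed by more than counting noise (chi-square per degree of freedom 1.72 to 15.5), so each counted as 1 sample. The labels do not say that the 3 libraries of a group came from separate cultures, and p-values then measure only the spread between these samples, which may be technical. No spike-in is recorded, so every change is relative to the typical gene of its library, and a change in total RNA per cell would not show.

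Counts were tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (13475), TMM scaling, a quasi-likelihood fit with robust=TRUE over all 9 libraries, a two-sided F test per comparison, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common biological coefficient of variation was 0.0784. CPM values are TMM-normalised. The counting interval of a ratio with few counts is exact at 95% and covers counting error only. On simulated counts with known changes (13360 genes, changed and unchanged), the test recovered 63.2%, 90.8% and 100% of changes of 0.5, 1 and 2 on the log2 scale for DC-1-170, 54.4%, 93.9% and 100% for DC-1-192, and 58.5%, 93.9% and 100% between the compounds, with 12 false calls of 180, 14 of 178 and 24 of 357. Changes near 0.5 or less were therefore often missed at this depth.

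Gene lists written before the data were examined were tested with camera (limma 3.58.1) on voom-weighted log2 CPM, with a preset inter-gene correlation of 0.01 and adjustment over 72 tests, 24 lists in 3 comparisons. They covered NF-kB targets and pathway components, p53 targets, DNA repair, BCL2 family and apoptosis, immediate early genes, the unfolded protein response, ATF4 targets, plasma cell and myeloma identity, ribosome biogenesis, cytosolic ribosomal proteins, replication-dependent histones, G2/M, G1/S and DNA replication, interferon-stimulated genes, heat shock, NRF2, cholesterol synthesis, glycolysis and hypoxia, the proteasome, RNA polymerase II transcription and elongation, snoRNA hosts and transcripts prone to nonsense-mediated decay, markers of other cell types, and all genes named ZNF with a number. None of the 13 mitochondrially encoded genes of a further list was among the rows used here. Where a list is given with 1 pair of counts, adjustment over the list alone gave the same. No camera call held with an estimated correlation, where adjusted p ran from 0.086 to 0.80. With simulated counts for DC-1-170 against untreated cells, the p from limma's camera was 2.3e-33 for a planted list of 40 genes. It was 0.0054 for a list of 39 genes drawn at random from the others, a call not planted, though genes simulated as changed could be among them. Of 200 random lists of unchanged genes 0% passed 0.05. Genes were simulated independently, so this gives no rate of false calls for lists whose members vary together. Gene length was the span of the gene's transcript in the files, taken in 10 equal classes.

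The genes named follow a rule fixed before the data were examined: the 12 largest rises and 12 largest falls for each compound and the 10 largest each way between compounds, among genes passing the test with a mean of at least 5 CPM in 1 of the 2 groups compared, no overlap between groups and a symbol that is not a clone or small RNA name, up to 4 members of each list with the smallest p and up to 2 with the highest CPM, and MYC, IRF4, MCL1, NFKBIA, RELA, RELB, NFKB1, NFKB2 and CDKN1A. Some genes that the rule selects are not reported here. RN45S, RMRP, RPPH1 and the neighbours of named genes were chosen after their values were seen.

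Alternatives fixed beforehand were DESeq2's size factors, upper-quartile and library-total scaling, no filter or a CPM of 1 in 3 libraries, DESeq2 1.42.0 and limma-voom, fits of 6 libraries, the replicate number as a block, sums over transcripts, each replicate left out, fry and exon length. Fry tests a list against no change, whereas camera tests it against the other genes, so a call lost with fry answers a different question. After the data were seen 4 more were added: RN45S out of the library totals, RN45S as a covariate, thinning to 1 depth, and the 3 libraries with over 40% RN45S left out. The last left only replicate 2 of DC-1-192, so the spread within that group could not be measured there. The neighbour test used logistic models (statsmodels 0.14.6) over 10194 genes, leaving out 2947 that overlap another gene. A neighbour was a gene of at least 5 CPM in untreated cells within 10 kb, and the model recovered 2.94 for an odds ratio set to 3 and 1.14 for one set to 1. GC content came from reference sequences of the GENCODE transcripts linked to each gene's RefSeq transcript, averaged where several were linked.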

Results

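JJN3 is a human plasma cell leukaemia line, grown in suspension and used as a model of multiple myeloma. The series asked which transcripts change genome-wide when these cells meet either of 2 pyrrolobenzodiazepine monomers, a class of small molecules that bind in the minor groove of DNA. Cells were left untreated or exposed to DC-1-170 or DC-1-192 at 30 nM for 4 h, with 3 libraries per group and 9 in all. RNA depleted of ribosomal RNA was sequenced, and read counts were available for 23360 genes. The labels name no vehicle for the untreated cells. Gene counts came to between 12.6 M and 20.2 M per library. One transcript, RN45S, the precursor of ribosomal RNA, took 11.3% to 15.1% of them in untreated cells, 16.8% to 57.1% after DC-1-170 and 26.9% to 52.5% after DC-1-192. Of the larger read totals implied by the RPKM values, it took 3.55% to 4.66%, 5.10% to 16.5% and 7.90% to 15.2% respectively. Without RN45S the libraries held 13.6 M to 17.2 M, 6.18 M to 11.7 M and 6.93 M to 9.23 M gene counts respectively, so outside RN45S the treated cells were read less deeply. On the first principal component of all genes tested, RN45S included, with 62.1% of the variance, the groups followed the order untreated, DC-1-170, DC-1-192. No library lay among those of another group.

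After DC-1-170, MYC transcripts fell from 301 ± 11 to 112 ± 6.1 CPM (TMM-normalised counts, scaled per M; mean ± SD, n = 3 here and below), a log2 fold change of −1.43 ± 0.07 (SE). MYC, at chromosome 8:128748315-128753680 in hg19, encodes a transcription factor that promotes cell growth and is often deregulated in myeloma. Of 46 replication-dependent histone genes, which encode the proteins that package newly copied DNA, 45 fell (limma camera adjusted p = 0.21 with an estimated correlation). HEXIM1, an inhibitor of the elongation kinase P-TEFb, went the other way, from 48.6 ± 1.9 to 184 ± 3.6 CPM (log2 fold change 1.92), and so did POLR2A, the largest subunit of RNA polymerase II (1.58), and the chromatin reader BRD2 (1.19). The plasma cell regulator IRF4 rose slightly, from 555 ± 12 to 671 ± 6.3 CPM (log2 fold change 0.27).

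Of 13475 genes tested, 5455 differed between DC-1-170 and untreated cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 2649 higher and 2806 lower. Changes of at least 2-fold were seen in 574 of the higher and 464 of the lower genes. The called genes were 40.5% of all genes tested, the background for the counts of list members below. In 50.2% of the tested genes the 3 libraries of one group lay above the 3 of the other, against 10% by chance. MYC passed with an adjusted p of 3.2e-11, HEXIM1 with 1.9e-13 and IRF4 with 6.8e-04. Scaling by library totals alone left 2943 calls, 320 higher and 2623 lower (10.9% higher, against 48.6%), as RN45S then counts towards the depth of each library, and upper-quartile scaling gave 3199 higher and 2555 lower (55.6%). The spread behind these p-values is that between the libraries sequenced, since nothing states that the 3 of a group came from separate cultures.

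**Figure D1:**
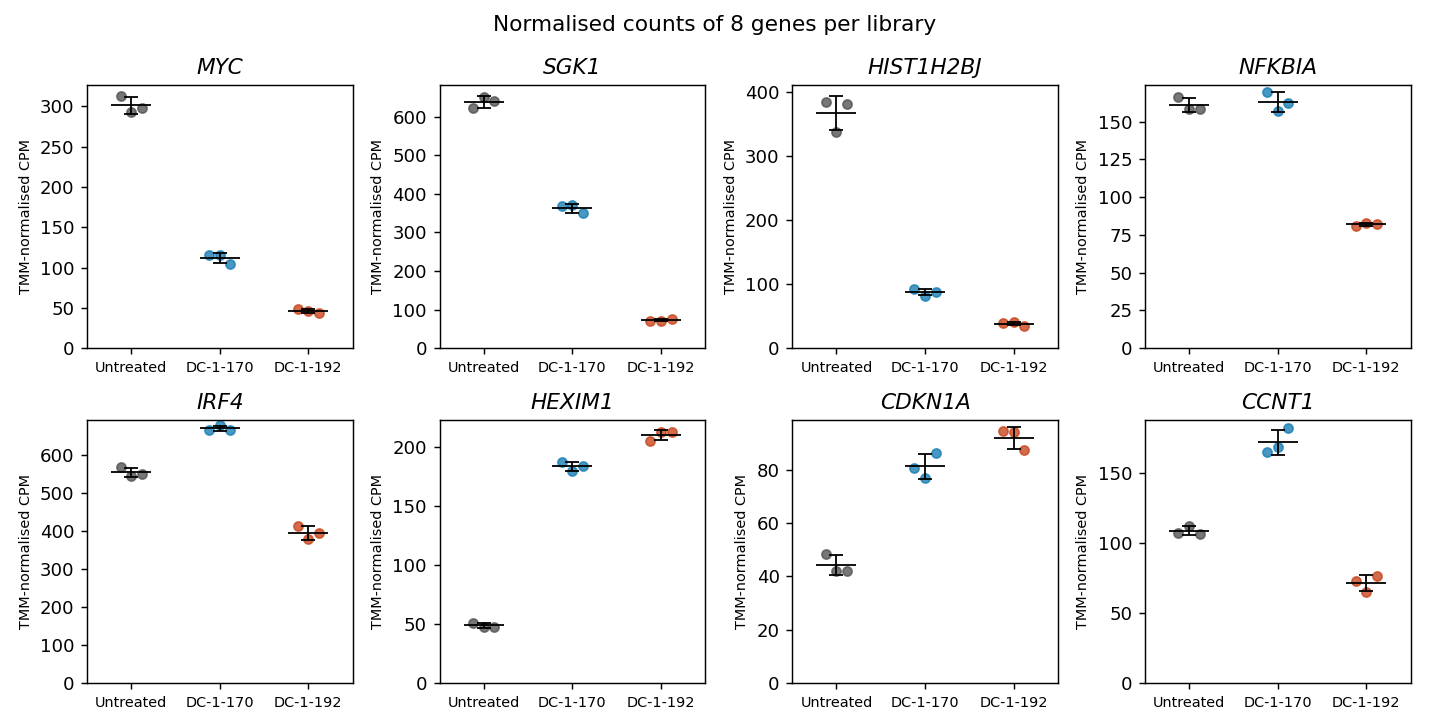
TMM-normalised CPM of MYC, SGK1, HIST1H2BJ, NFKBIA, IRF4, HEXIM1, CDKN1A and CCNT1 on the vertical axes, by group on the horizontal axes. Points are libraries, bars the mean and SD of 3. MYC stands at means of 301, 112 and 46.1 and HEXIM1 at 48.6, 184 and 210 in untreated, DC-1-170 and DC-1-192 cells, while IRF4 and CCNT1 lie above the untreated level after DC-1-170 and below it after DC-1-192.

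Of 46 replication-dependent histone genes tested, 45 fell after DC-1-170 and none rose, with a median log2 fold change of −1.09, and 45 also fell when adjusted over the list alone. HIST1H2BJ (chromosome 6:27100095-27100575) dropped from 367 ± 26 to 87.0 ± 4.8 CPM, HIST1H4B changed by −1.44 on the log2 scale, and the abundant linker histones HIST1H1C and HIST1H1E by −1.13 and −1.08. The list differed from other genes by camera (adjusted p = 9.5e-38, down), but with an adjusted p = 0.21 with an estimated correlation, as histone transcripts vary together between libraries (estimated correlation 0.57). Many of these genes have near-identical copies within their histone family, so the assignment of reads to single members is uncertain. Among G2/M genes 22 of 31 fell and 2 rose (22 and 2 adjusted over the list alone), including the mitotic kinase AURKA (log2 fold change −1.04), the spindle motor KIF20A (−0.75, overlapping CDC23 on the other strand), the cyclin CCNB1 (−0.46) and the topoisomerase TOP2A (−0.29). Its camera adjusted p was 6.2e-06, and adjusted p = 0.21 with an estimated correlation. Genes of G1/S and DNA replication went up, 17 of 32 against 3 down (18 and 4 adjusted over the list alone), led by E2F1 (1.03) and CCNE1 (0.75), which promote entry into S phase. Here camera gave an adjusted p of 0.0023, and adjusted p = 0.21 with an estimated correlation.

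Targets of ATF4, the transcription factor of the integrated stress response, rose after DC-1-170 in 16 of 29 cases and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 7e-04, and adjusted p = 0.21 with an estimated correlation). CEBPG rose by 0.57 on the log2 scale and the amino acid transporter SLC7A5 by 0.35, whereas the single member that fell was DDIT4 (−0.84), an inhibitor of mTORC1. Of 75 cytosolic ribosomal protein genes 12 rose by small amounts, none fell and 63 did not pass (6 rose adjusted over the list alone; RPL30 0.26), with a camera adjusted p of 0.0027 and adjusted p = 0.76 with an estimated correlation. That last call was lost with fry (limma, adjusted p = 0.27), without untreated replicate 1 (camera adjusted p = 0.15) and without DC-1-170 replicate 1 (adjusted p = 0.45).

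Other lists held members that moved both ways after DC-1-170 and were not called by camera. Immediate early genes split into 9 that rose and 11 that fell of 28, with DUSP5 at −1.19 and SGK1 at −0.81 on the log2 scale and ATF3 at 1.63. Their median was 0.12, their mean −0.01 and the camera direction down (adjusted p = 0.61). Of 36 genes for RNA polymerase II transcription and elongation 9 rose and 12 fell (12 and 12 adjusted over the list alone), with the kinase CDK13 at −1.05 and the Mediator subunit MED13 at −0.78 against HEXIM1, POLR2A and BRD2 above. Among 28 p53 targets 9 rose and 5 fell (10 and 5 adjusted over the list alone). PMAIP1, which encodes the death-promoting protein NOXA, rose by 1.21, SERTAD1 by 1.29 and the cell cycle inhibitor CDKN1A by 0.88, from 44.2 ± 3.8 to 81.3 ± 4.8 CPM, while MDM2 changed by −0.26 and BTG2 by −0.33. Plasma cell and myeloma identity genes fell in 9 of 29 cases and rose in 6 (10 and 6 adjusted over the list alone), the lower ones including the lymphoid regulators IKZF1 (−0.95), IKZF3 (−0.95) and MEF2C (−0.88).

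NF-kB target genes fell in 9 of 26 cases and rose in 3 after DC-1-170 (camera adjusted p = 0.11), and pathway components fell in 10 of 28 and rose in 2 (adjusted p = 0.075). Of the subunits, NFKB1 fell (log2 fold change −0.48). RELA (0.08), RELB (0.02) and NFKB2 (0.05) did not pass, and neither did the inhibitor NFKBIA (0.02; 161 ± 4.8 against 163 ± 6.6 CPM). The survival factor MCL1 stood at 345 ± 7.3 and 335 ± 19 CPM (log2 fold change −0.04, adjusted p = 0.57).

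Among genes with a mean of at least 5 CPM in 1 of the groups compared, here and below, the largest rises after DC-1-170 were those of CCDC168 (log2 fold change 4.16), AOC3 (3.84), APOE (3.54), RHBDL1 (3.53), ENAM (3.37), HAP1 (3.25), BZRAP1 (3.21), CCDC11 (2.97), ZNF425 (2.80), ADAMTSL4 (2.72), C8orf73 (2.66) and PAQR6 (2.66). BZRAP1 (chromosome 17:56378594-56406152) was the most abundant, going from 9.82 ± 0.086 to 91.3 ± 6.2 CPM. BZRAP1 overlaps an antisense gene, LOC100506779, and the use of strand in the counting is not stated. An expressed gene ended within 10 kb upstream on the same strand in 7 of these 12, as TOMM40 does 2.09 kb before APOE. HEXIM1 has such a neighbour too, ACBD4, 3.14 kb upstream, though ACBD4 stood at only 6.24 CPM in untreated cells. The largest falls were HIST1H2BM (−2.37), the Ikaros family factor IKZF2 (−2.32), LRRC1 (−2.30), the neuronal RNA-binding protein ELAVL2 (−2.29), MAP4K3 (−2.26), TMEM200A (−2.16), SEMA6D (−2.14), the sodium channel subunit SCNN1G (−2.13), ZSWIM6 (−2.13), the phosphatase CDC14A (−2.10), STARD13 (−2.08) and HIST1H2BJ (−2.08).

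Falls after DC-1-170 were concentrated in long genes. In the 10% of genes with the longest genomic span, a median of 198 kb, 59.4% fell and 2.15% rose, with a median log2 fold change of −0.42. In the 10% with the shortest span, a median of 1.84 kb, 10.5% fell and 21.8% rose (median 0.15), and the share that rose was highest, 33.0%, in the class with a median span of 8.81 kb (median 0.19). Spearman's rho between span and fold change across genes was −0.43, −0.28 without a filter on low counts and −0.272 with exon length in place of span, and genes are not independent replicates. The longest 10% differed from other genes by camera (p = 5.4e-31), and p = 0.0012 with an estimated correlation. For the shortest 10% camera gave p = 0.016, up, and p = 0.41 with an estimated correlation.

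**Figure D2:**
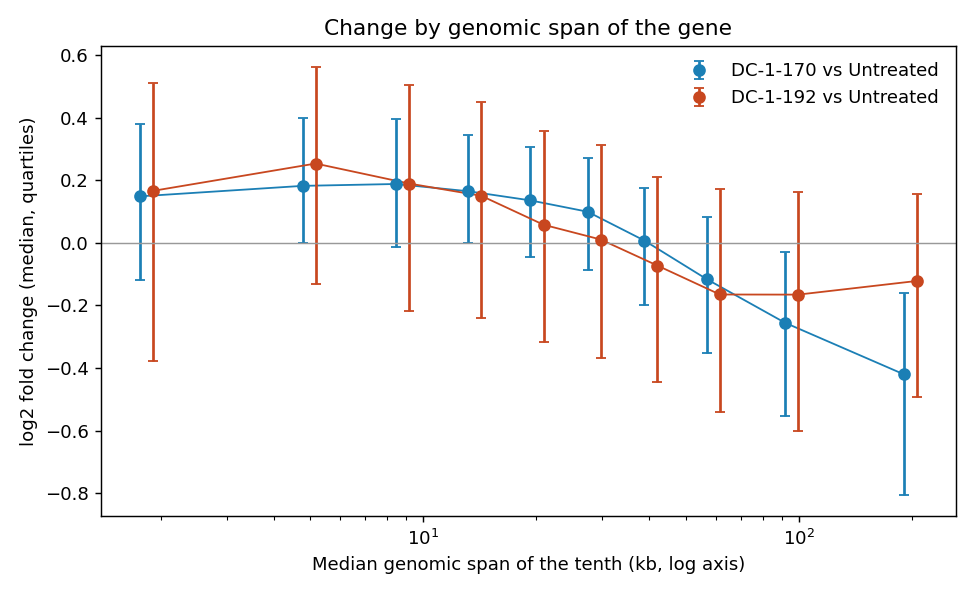
Median log2 fold change against untreated cells (vertical axis) for 10 equal classes of the tested genes by genomic span (median span in kb, log axis), with bars for the quartiles. DC-1-170 stands at 0.15 in the shortest class, 0.19 in the third and −0.42 in the longest, while DC-1-192 stands at −0.17 in the class before the last and −0.12 in the last.

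DC-1-192 lowered MYC further, to 46.1 ± 2.9 CPM, a log2 fold change of −2.71 ± 0.07 (SE). SGK1, a survival kinase, fell from 639 ± 15 to 72.0 ± 2.3 CPM (−3.15), and RGS1, a regulator of G protein signalling in B cells, from 166 ± 11 to 12.6 ± 1.9 CPM (−3.72). IRF4 fell from 555 ± 12 to 395 ± 18 CPM (−0.49), MCL1 to 236 ± 1.7 CPM (−0.55) and NFKBIA to 82.0 ± 0.76 CPM (−0.97). HEXIM1 again rose, to 210 ± 4.5 CPM (2.11). Of 390 zinc finger genes 254 fell and 33 rose, and of 46 histone genes 45 fell (limma camera adjusted p = 0.15 and adjusted p = 0.21 with an estimated correlation).

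In total 7874 genes differed between DC-1-192 and untreated cells (edgeR, adjusted p under 0.05), 3889 higher and 3985 lower, and 849 and 1086 of these by at least 2-fold. The called genes were 58.4% of all genes tested. Groups did not overlap in 63.1% of genes, against 10% by chance. MYC passed with an adjusted p of 1.4e-15, SGK1 with 1.5e-17, IRF4 with 6.2e-07, MCL1 with 2.7e-07 and NFKBIA with 3.2e-10. Scaling by library totals alone left 485 higher and 5414 lower (8.22% higher, against 49.4%), and upper-quartile scaling gave 4827 higher and 3395 lower (58.7%).

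Of 390 tested genes named ZNF with a number, most of which encode DNA-binding zinc finger proteins, 254 fell and 33 rose after DC-1-192 (256 and 34 adjusted over the list alone), with a median log2 fold change of −0.63. ZNF217 went from 113 ± 2.8 to 24.9 ± 1.1 CPM (−2.18), ZNF45 changed by −2.38 and ZNF644 by −1.70, while the abundant ZNF24 (−0.10) did not pass. After DC-1-170, by contrast, 100 ZNF genes fell, among them ZNF407 (−1.50), and 66 rose (100 and 68 adjusted over the list alone). The list was called for DC-1-192 (camera adjusted p = 1.3e-12), though with adjusted p = 0.15 with an estimated correlation, and not for DC-1-170 (adjusted p = 0.30). Histone genes fell in 45 of 46 cases, none rising (45 adjusted over the list alone; median −1.70), with HIST1H2BJ at 38.4 ± 2.8 CPM (−3.25) and HIST1H2BG at −2.46, under the same doubt over near-identical copies. Their camera adjusted p was 1.3e-32, and adjusted p = 0.21 with an estimated correlation. G2/M genes fell in 21 of 31 cases and rose in 1 (21 and 1 adjusted over the list alone; camera adjusted p = 3.2e-05, and adjusted p = 0.23 with an estimated correlation), with AURKA at −1.67, KIF2C at −1.06 and CCNB1 at −1.03. The G1/S list did not move one way, with 10 up and 12 down of 32 (camera adjusted p = 0.79), E2F1 at 0.73 and the replication checkpoint gene CLSPN at −0.88.

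Of 26 NF-kB target genes 13 fell and 3 rose after DC-1-192 (13 and 3 adjusted over the list alone). The ubiquitin-editing inhibitor TNFAIP3 went from 196 ± 4.7 to 53.6 ± 1.9 CPM (log2 fold change −1.87), the chemokine CCL3 changed by −1.85, the transcription factor IRF1 by −1.26 and the invariant chain CD74 by 0.54. Among 28 pathway components 16 fell and 2 rose (16 and 2 adjusted over the list alone), including the NF-kB-inducing kinase MAP3K14 (−1.75), which overlaps LOC100133991 on the other strand, BIRC3 (−1.21) and RIPK1 (−0.93). Camera called both lists, at adjusted p = 0.0040 for targets and 0.0043 for components, and with an estimated correlation these became adjusted p = 0.21 and adjusted p = 0.20. NFKB1 changed by −0.33 (adjusted p = 0.0014), whereas RELA (0.01), RELB (0.20) and NFKB2 (−0.07) did not pass.

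Heat shock genes fell in 12 of 21 cases and rose in 2 after DC-1-192 (12 and 2 adjusted over the list alone; camera adjusted p = 0.0057, and adjusted p = 0.21 with an estimated correlation). The constitutive chaperone HSPA8 went from 5018 to 2687 CPM (log2 fold change −0.90) and its partner DNAJB1 changed by −1.08, while HSPB1 rose (0.80). Ribosome biogenesis genes fell in 16 of 35 cases and rose in 6 (16 and 6 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.33 with an estimated correlation), with the RNA polymerase I subunit POLR1B at −0.97, WDR43 at −0.84 and UTP20 at −0.81. That call was lost with RN45S as a covariate (adjusted p = 0.19) and with upper-quartile scaling (adjusted p = 0.055). Hosts of small nucleolar RNAs and transcripts prone to nonsense-mediated decay fell in 15 of 24 cases and rose in 5 (16 and 5 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.21 with an estimated correlation), with SNHG12 at −1.90, GAS5 at −1.31 and SNHG3 at −0.74. These 3 values are uncertain, since SNHG12 and GAS5 overlap TRNAU1AP and LOC100506046 on the other strand and SNHG3 overlaps RCC1 on its own. Cytosolic ribosomal protein genes rose in 34 of 75 cases with none falling (32 adjusted over the list alone), by small amounts such as 0.47 for RPLP2, 0.46 for RPL3 and 0.40 for RPL30. Their camera adjusted p was 2.1e-04, and adjusted p = 0.69 with an estimated correlation, and fry did not call them (adjusted p = 0.14). ATF4 targets rose in 16 of 29 cases and fell in 4 (17 and 5 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.27 with an estimated correlation), with ATF4 itself at 0.67, the cystine transporter SLC7A11, which overlaps the antisense gene LOC641364, at 1.24 and DDIT4 at −2.28.

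Among lists not called for DC-1-192, immediate early genes rose in 12 and fell in 13 of 28 cases (median 0.04, mean −0.22, camera down, adjusted p = 0.64), with DUSP5 at −2.38, DUSP6 at −2.37 and ATF3 at 2.10. Of 36 genes for RNA polymerase II transcription 8 rose and 19 fell (adjusted p = 0.11), among the latter the cyclins CCNL1 (−1.37), CCNT2 (−1.48) and CCNT1 (−0.61). Of 28 p53 targets 8 rose and 10 fell (median 0.02, mean −0.04, camera down, adjusted p = 0.90). PMAIP1 rose by 1.58 and CDKN1A by 1.06, and PPM1D and BTG2 changed by −1.23 and −0.95. BCL2 family and apoptosis genes fell in 12 of 24 cases and rose in 3 (adjusted p = 0.11), with BCL2L1 at −0.66 and BCL2 at 0.37. After DC-1-170 they fell in 6 and rose in 3 (adjusted p = 0.44). Genes for nucleotide excision and Fanconi anaemia repair fell in 14 of 39 cases and rose in 6 (adjusted p = 0.24), with FAN1, which overlaps MTMR10 on the other strand, at −0.95 and ERCC4 at −0.91, and after DC-1-170 fell in 7 and rose in 4 (adjusted p = 0.71), with FANCC at −0.95. Plasma cell identity genes rose in 11 and fell in 7 of 29 cases (median 0.05, mean 0.06, camera down, adjusted p = 0.91). PRDM1, the regulator of plasma cell differentiation, changed by −1.65 and the joining chain gene IGJ by 0.41. CD79A rose from 0.12 ± 0.078 to 2.04 ± 0.42 CPM (4.03) and lies 5.71 kb downstream of RPS19 on the same strand.

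**Figure D3:**
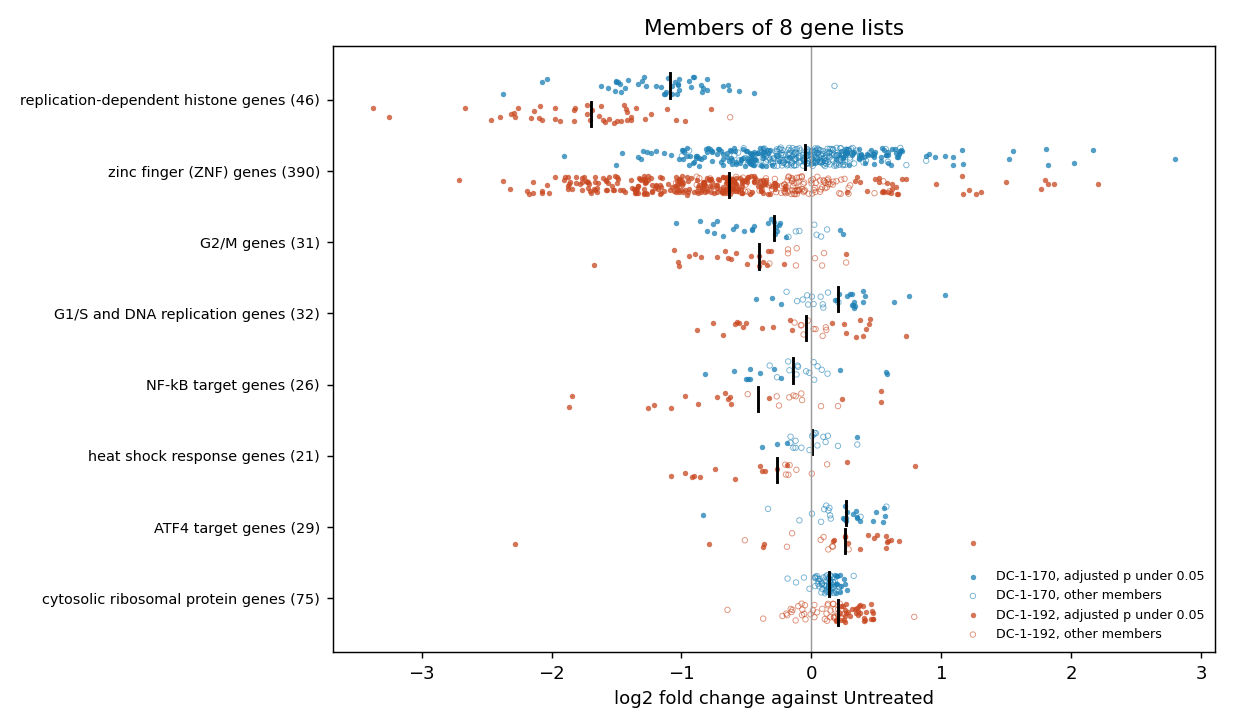
Log2 fold change against untreated cells (horizontal axis) of each tested member of 8 gene lists, the number of members in parentheses, for DC-1-170 and DC-1-192. Filled points passed an adjusted p of 0.05, open points did not, and black bars are medians. The histone medians lie at −1.09 and −1.70, and the ZNF medians at −0.05 and −0.63.

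The largest rises after DC-1-192 were FAM83E, PYGM (log2 fold change 5.73), CPT1C (5.46), MYO1G (5.25), ICAM4 (5.19), APOE (5.09), DHX58 (4.81), VHLL (4.64), GPR179 (4.54), C8orf73 (4.19), BZRAP1 (4.19) and KIAA1875 (4.08). FAM83E (chromosome 19:49103857-49116694) had 2 counts in the 3 untreated libraries together, which gives a ratio of 186 with a 95% counting interval of 50.7 to 1542, and it overlaps SPACA4. PYGM, muscle glycogen phosphorylase, went from 0.292 ± 0.13 to 15.9 ± 1.4 CPM and BZRAP1 to 179 ± 8.2 CPM. In 10 of the 12 an expressed gene ended within 10 kb upstream on the same strand, such as SF1 3.89 kb before PYGM, PRMT1 2.66 kb before CPT1C and KAT2A 0.377 kb before DHX58. The largest falls were SCNN1G (−4.22), the haematopoietic GTPase RHOH (−4.04), RGS1 (−3.72), RND3 (−3.38), HIST1H2BM (−3.38), HIST1H2BJ (−3.25), SGK1 (−3.15), MYH15 (−3.09), ARHGEF3 (−3.08), ZNF624 (−2.72), MYC (−2.71) and KIAA0232 (−2.70). ARHGEF3 overlaps the antisense gene SPATA12, whose reads cannot be told apart from its own without strand.

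Long genes fell less after DC-1-192. In the longest 10% of genes 35.5% fell and 14.2% rose, with a median log2 fold change of −0.12, and rho between span and fold change was −0.23. At fixed transcript GC content it was −0.114, against −0.234 in the same genes. In these genes GC content itself had a rho of 0.367 with the fold change after DC-1-192, and 0.306 after DC-1-170. Camera gave p = 0.0024 for the longest 10%, and p = 0.185 with an estimated correlation.

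Set against each other at the same dose and time, the 2 compounds differed in the levels of several regulators. SGK1 was 5.05-fold and RGS1 5.30-fold lower after DC-1-192 than after DC-1-170, and MYC 2.43-fold lower (log2 difference −1.28 ± 0.07, SE). NFKBIA was 1.99-fold lower and IRF4 1.70-fold lower (log2 differences −0.99 and −0.76). CDKN1A (log2 difference 0.18, 95% interval 0.02 to 0.34) and AOC3 (0.16, −0.15 to 0.47) did not pass, which leaves differences of the size of these intervals open.

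Between DC-1-192 and DC-1-170, 4728 genes differed (edgeR, adjusted p under 0.05), 2027 higher and 2701 lower after DC-1-192, of which 273 and 454 by at least 2-fold. MYC passed with an adjusted p of 3.5e-10, SGK1 with 5.3e-15, IRF4 with 1.3e-08 and NFKBIA with 2.1e-09. The called genes were 35.1% of all genes tested. Groups did not overlap in 48.0% of genes, against 10% by chance. Scaling by library totals alone left 958 calls (16.7% higher, against 42.9%), and without DC-1-170 replicate 2 the genes higher after DC-1-192 numbered 1338. No conclusion is drawn from calls without the 3 libraries with over 40% RN45S, since only replicate 2 of DC-1-192 then remained. With upper-quartile scaling 2780 were higher and 2328 lower (54.4% higher).

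Zinc finger genes were lower after DC-1-192 than after DC-1-170 in 242 of 390 cases and higher in 11 (252 and 17 adjusted over the list alone; camera adjusted p = 5.7e-20, and adjusted p = 0.086 with an estimated correlation), including ZNF398 (log2 difference −1.44) and ZNF561 (−1.61). Histones were lower in 43 of 46 and higher in none (46 adjusted over the list alone; camera adjusted p = 5.3e-23, and adjusted p = 0.21 with an estimated correlation). NF-kB targets were lower in 10 of 26 and higher in 1 (10 and 1 adjusted over the list alone), components lower in 10 of 28 and higher in none (11 and 1 adjusted over the list alone), with camera adjusted p of 0.0032 and 0.012, and adjusted p = 0.21 for both with an estimated correlation. TNFAIP3 differed by −1.58, IRF1 by −0.77, MAP3K14 by −1.02 and RIPK1 by −0.76. G1/S genes were lower in 15 of 32 and higher in none (16 adjusted over the list alone; camera adjusted p = 2.1e-04, and adjusted p = 0.21 with an estimated correlation), with CDC6 at −0.81. Heat shock genes were lower in 12 of 21 and higher in 1 (12 and 2 adjusted over the list alone), ribosome biogenesis genes lower in 18 of 35 and higher in 2 (20 and 2), and snoRNA hosts lower in 14 of 24 and higher in 1 (14 and 1). For these camera gave adjusted p of 6.8e-04, 2.0e-04 and 1.4e-04, and with an estimated correlation adjusted p = 0.21, adjusted p = 0.21 and adjusted p = 0.20. DNAJB1 (−0.96), RRS1 (−0.94) and GAS5 (−0.73) were examples. Genes for RNA polymerase II transcription were lower in 16 of 36 and higher in 5 (17 and 5 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.21 with an estimated correlation). Ribosomal protein genes were higher in 16 of 75 and lower in none (10 adjusted over the list alone; camera adjusted p = 0.036, and adjusted p = 0.80 with an estimated correlation), a call lost with fry (adjusted p = 0.64) and without DC-1-170 replicate 2 (adjusted p = 0.11), DC-1-170 replicate 3 (0.74) or DC-1-192 replicate 2 (0.11). The G2/M list was not called (7 lower of 31, 6 adjusted over the list alone; adjusted p = 0.16), nor were ATF4 targets (7 higher and 7 lower of 29; median 0.03, mean −0.08, camera up, adjusted p = 0.79), plasma cell identity genes (12 higher and 5 lower of 29, 12 and 9 adjusted over the list alone; adjusted p = 0.31), immediate early genes (7 higher and 13 lower of 28, 9 and 13 adjusted over the list alone; median 0.08, mean −0.21, camera down, adjusted p = 0.17), p53 targets (4 higher and 11 lower of 28, 6 and 11 adjusted over the list alone; adjusted p = 0.11), apoptosis genes (3 higher and 10 lower of 24; adjusted p = 0.16) or repair genes (4 higher and 10 lower of 39; adjusted p = 0.31).

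The genes furthest above in DC-1-192 cells were CPT1C (log2 difference 4.03), PITPNM2 (2.69), SNX32 (2.66), PYGM (2.56), ICAM5 (2.53), MYO1G (2.46), SEMA3B (2.45), DHX58 (2.42), FAM83E (2.35) and ICAM4 (2.01). PITPNM2 overlaps the antisense gene LOC100507091. Furthest below were RGS1 (−2.41), SGK1 (−2.34), the chromatin factor EPC1 (−2.12), NBPF4 (−2.06), the TGF-beta pseudoreceptor BAMBI (−2.03), TAGAP (−1.98), ZNF697 (−1.96), CXorf21 (−1.94), ENAM (−1.90) and ZNF567 (−1.89). EPC1 illustrates a fall called for DC-1-192 alone, at 31.0 ± 1.1, 28.6 ± 1.1 and 6.61 ± 0.72 CPM in untreated, DC-1-170 and DC-1-192 cells. In the longest 10% of genes 45.9% were higher after DC-1-192 than after DC-1-170 (median log2 difference 0.29; camera p = 1.1e-20, and p = 0.0037 with an estimated correlation). The rank correlation of span with this difference was 0.15, 0.254 at fixed transcript GC content, 0.036 without the 3 libraries with over 40% RN45S, 0.062 without a filter on low counts, 0.061 with DESeq2 and 0.071 with exon length in place of span. Without those 3 libraries only replicate 2 of DC-1-192 remained.

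Both compounds moved many genes alike. HEXIM1, POLR2A and PMAIP1 rose after both and MYC, AURKA and the histones fell after both. In all, 1913 genes were higher and 2189 lower after both compounds, where independent lists of these sizes would share 764.5 and 829.8. The same untreated libraries served both comparisons, and in 20 simulations with unchanged groups the same-direction calls averaged 0.1 (at most 1). Pearson's correlation of the fold changes across genes was 0.79 and their covariance 0.450, against 0.42 and 0.0127 in the simulations. These values argue against the fitted spread of the shared controls as the source of the overlap. Genes were simulated independently, and with 3 untreated libraries no split keeps a pair in each part. A deviation common to the untreated libraries therefore stays open as part of the excess. Among the 4102 genes called in the same direction, 1225 were moved further by DC-1-192, 313 further by DC-1-170, and 2564 showed no passing difference. A further 151 genes were called in opposite directions, 134 of them higher after DC-1-170 and lower after DC-1-192. With library totals alone 2614 genes were called in the same direction and 1 in opposite directions. The number in opposite directions was 81 without untreated replicate 3 and 49 with RN45S as a covariate.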

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

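The tests of treatment as the source of the span trend and of the RN45S share were chosen after the results were seen, as were the fits with RN45S as a covariate, with thinned libraries and without the 3 libraries with over 40% RN45S. In all, 151 genes were called in opposite directions by the 2 compounds, and each also differed between the compounds by the edgeR test of the difference itself. Among the genes named, 8 were of this kind, and each was higher than in untreated cells after DC-1-170 and lower after DC-1-192. The log2 differences between DC-1-192 and DC-1-170 were −1.27 for CCNT1, −1.81 for CCNT2 and −1.58 for CCNL1, all 3 cyclins of the transcription machinery. They were −1.19 for CCNE2, which overlaps INTS8 on the other strand, and −0.78 for CDC25A, which act at entry into S phase, −1.12 for the splicing kinase CLK1, −1.16 for the stress sensor SESN2 and −0.76 for IRF4.

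The falls of these 8 genes after DC-1-192 kept their calls under every alternative tried, although with library totals alone the shift of all genes lies in the same direction. The rises after DC-1-170 depended on the scaling. With library totals alone only 1 of all genes was called in opposite directions, so at most 1 of these 8 rises kept its call. Under other alternatives the rises of CCNL1, CCNT2, SESN2 and CLK1 were less secure as well. CCNL1 rose by 0.21 on the log2 scale (edgeR adjusted p = 0.022) and missed the threshold without untreated replicate 1 (0.12, adjusted p = 0.19), untreated replicate 3 (0.18, 0.14), DC-1-170 replicate 2 (0.19, 0.093) or DC-1-170 replicate 3 (0.20, 0.055). CCNT2 rose by 0.33 (adjusted p = 0.021) and missed it without the same libraries, with adjusted p of 0.11, 0.12, 0.091 and 0.082. CCNL1 also missed it with DESeq2 (adjusted p = 0.059), without a filter on low counts (0.059), with 6 libraries per fit (0.066) and after thinning (0.099), and CCNL1 and CCNT2 without the 3 libraries with over 40% RN45S (0.15 and 0.135). With RN45S as a covariate the rises of SESN2 (0.30, adjusted p = 0.098), CLK1 (0.16, 0.23), CCNL1 (0.15, 0.20) and CCNT2 (0.08, 0.64) did not pass either.

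After DC-1-170 genes fell more the longer their span, with a rho of −0.43 across genes. GC content as the whole source is argued against by a partial rho of −0.364 at fixed transcript GC content, against −0.435 in the same genes, residual ribosomal RNA by a rho of −0.452 with RN45S as a covariate, and lower depth by −0.434 after thinning to 1 depth. Treatment with DC-1-170 may account for it, as the trend within each DC-1-170 library, set against the untreated mean, was at most −0.372, below the lowest untreated library (−0.211), although the untreated libraries themselves ran from there to 0.252. The weaker trend after DC-1-192 was −0.193, −0.272 and −0.188 in its libraries, and the first and last of these lie within the untreated range. At fixed GC content its rho across genes went from −0.234 to −0.114, so GC content stays open as a source of much of that weaker trend. Whether fewer polymerases reached the ends of long genes was not tested, since the counts hold no positions within genes.

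Genes that rose at least 2-fold after DC-1-192 often lay close downstream of an expressed gene on the same strand, 36.2% of 665 against 11.3% of other genes. Gene density alone is argued against by the odds ratio of such a neighbour, 4.43 times (95% interval 3.05 to 6.44) that of a divergent neighbour, and GC content by an odds ratio of 3.69 with GC content and expression added. Transcription running past the end of the upstream gene stays open, with an odds ratio of 3.91 (3.06 to 5.01), and of 2.76 (2.13 to 3.59) after DC-1-170, and a candidate explanation of the rises in genes such as CPT1C, DHX58 and PYGM is that they are partly reads of this kind. The share of genes that rose declined from 23.0% with a gap of 0 to 2 kb to 3.95% beyond 50 kb, and a convergent neighbour had an odds ratio of 3.11, which counting without strand could give. A neighbour downstream on the same strand had one of 1.99 (1.48 to 2.68), and 1.48 (1.09 to 1.99) with GC content and expression added, which transcription past an upstream gene's end does not predict.

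RN45S took a larger share of the counts in the treated libraries. Uneven removal of ribosomal RNA may account for it, because within a treated group its highest over its lowest level exceeded that of RMRP and RPPH1 by at least 2.22 times, and by 6.19 times after DC-1-170. In the untreated group that ratio was 1.01, so uneven removal was not seen there. Treatment stays open too, with an exact two-sided permutation p of 0.0238 for 6 treated against 3 untreated libraries, while 3 against 3 gave 0.1 for each compound, the smallest p that design allows.

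With 3 libraries per group there are 10 splits of the 6 libraries of a comparison, too few for a share under 0.05. The real split gave 5455, 7874 and 4728 genes for DC-1-170, DC-1-192 and DC-1-192 against DC-1-170, and was the 1 split of 10 with as many in each case. The highest of the others was 0 by edgeR in each comparison, with 83 to 852, 65 to 659 and 115 to 716 genes at an unadjusted p under 0.05 where the real splits gave 6544, 8450 and 6073. For gene lists called by camera at the preset correlation, the real splits gave 5, 10 and 10 and the highest others 7, 8 and 9, and 3 of 10, 1 of 10 and 1 of 10 splits gave as many as the real one. List calls at the preset correlation were therefore made in the other splits as well. Each of those splits mixes the groups, so part of the real difference remains and part adds to the spread within each side. Neither the 0 genes nor the list calls of the other splits therefore measure how often false calls arise.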

How the results depend on the processing

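The fits with RN45S out of the totals or as a covariate, thinned, and without the 3 libraries with over 40% RN45S were chosen after the data were seen, the other alternatives before. With library totals alone the median of all genes moved by −0.453, −0.600 and −0.145 for DC-1-170, DC-1-192 and DC-1-192 against DC-1-170, because RN45S then counts towards the depth, and values below are relative to that shift. Calls were then 2943 (320 higher) for DC-1-170, 485 higher for DC-1-192, and 958 between compounds (160 higher, 798 lower), with 2614 shared by both compounds and 1 in opposite directions. Without the 3 libraries with over 40% RN45S, 2818 genes differed between compounds (1107 higher, 1711 lower), with fewer samples, and 80 were called in opposite directions, against 49 with RN45S as a covariate. Without the 3 libraries only replicate 2 of DC-1-192 remained, so the spread within that group could not be measured. No conclusion is drawn from the calls of that fit. With each other scaling, filter and test the totals lay within 1.5 times the reported ones.

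The correlation between the compounds was 0.621 without a filter, 0.654 with DESeq2, 0.777 with 6 libraries per fit, 0.816 with the RN45S covariate and 0.743 without the 3 libraries. The longest 10% of genes after DC-1-192 (median −0.14 relative to that of all genes) missed the threshold with an estimated correlation (p = 0.185). With each replicate left out in turn the correlation ran from 0.778 to 0.816 and opposite calls from 81 (without untreated replicate 3) to 142. With each replicate of the groups compared left out, genes higher after DC-1-192 than after DC-1-170 ran from 1338 (without DC-1-170 replicate 2) to 1793, and calls from 4252 to 5687 for DC-1-170, 7046 to 7955 for DC-1-192 and 3540 to 4283 between compounds. Leaving out an untreated library gave 1917 to 2394 higher and 2584 to 2872 lower between compounds, and leaving out a DC-1-170 library gave 3822 to 4001 higher and 3932 to 4053 lower for DC-1-192.

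With the replicate number as a block the calls were 4644, 7322 and 3998, with 109 in opposite directions, and no list call changed. Libraries with the same number did not deviate together (correlations −0.242 to 0.0129), so the numbers gave no sign of pairing. Deviations from means of 3 libraries cannot show that the samples were unpaired.

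Of 9057 values of named genes under alternatives, 299 that had passed no longer did, 113 of them with library totals alone, and 36 newly passed. The 32 that turned sign had not passed. For NFKBIA after DC-1-170 they were −0.0034 without a filter, −0.0045 with DESeq2, −0.0075 with 6 libraries and −0.0099 without the 3 libraries, and −0.019 to 0.045 with a replicate left out. For RELB after DC-1-170 they were −9.8e-05 with DESeq2, −0.0015 with 6 libraries and −0.030 without the 3 libraries, and −0.107 to 0.143 with a replicate left out. For RELA after DC-1-192 they were −0.021 without a filter, −0.0053 with DESeq2 and −0.0036 with sums over transcripts, and −0.074 to 0.042 with a replicate left out. With a replicate left out RELA ran from −0.012 to 0.132 after DC-1-170, NFKB2 from −0.034 to 0.094 and MYH15 from −0.353 to 0.039. NFKB2 after DC-1-192 was 0.016 with upper-quartile scaling and 0.038 with the RN45S covariate, and ZNF567 after DC-1-170 −0.046 with the latter. MAP4K3 between compounds was −0.068 with the RN45S covariate and −0.219 without the 3 libraries. With a replicate left out the difference between compounds ran from −0.074 to 0.325 for MAP4K3, −0.045 to 0.562 for CDC14A and −0.129 to 0.017 for RELA. The cause was not tested.

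Of 25 list calls 10 were lost with library totals, 3 (ribosomal proteins) with fry, 25 with an estimated correlation, and at most 1 under any other alternative. Pseudocount alternatives, meant for files without counts, were not run.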

Other observations

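Several further gene groups held called members without a camera call in any comparison. Of all genes tested 40.5% were called after DC-1-170, 58.4% after DC-1-192 and 35.1% between compounds. A share of called members near or below these does not set a group apart. Cholesterol synthesis genes rose in 9 of 23 cases with none falling after DC-1-170 (9 adjusted over the list alone; limma camera adjusted p = 0.11), with IDI1, an isoprenoid enzyme gene that overlaps IDI2-AS1 on the other strand, at 0.75 on the log2 scale. After DC-1-192 10 rose and 8 fell (10 and 8 adjusted over the list alone; median 0.08, mean −0.01, camera up, adjusted p = 0.80), with IDI1 at 0.42. Between compounds 10 were lower and 1 higher after DC-1-192 (adjusted p = 0.13). Glycolysis and hypoxia genes rose in 7 and fell in 3 of 30 cases after DC-1-170 (4 and 3 adjusted over the list alone; adjusted p = 0.43) and rose in 15 and fell in 7 after DC-1-192 (median 0.16, mean −0.0003, camera up, adjusted p = 0.35), with the glucose transporter SLC2A1, which overlaps FLJ32224 on the other strand, at −1.08 and the phosphofructokinase PFKM at 0.55 after DC-1-192. Between compounds 5 were higher and 6 lower (6 and 6 adjusted over the list alone; median 0.04, mean −0.05, camera up, adjusted p = 0.79). NRF2 oxidative stress genes rose in 10 and fell in 6 of 24 cases after DC-1-170 (10 and 7 adjusted over the list alone; adjusted p = 0.39), and rose in 10 and fell in 7 after DC-1-192 (adjusted p = 0.79), while NFE2L2, which encodes NRF2 itself, changed by −0.39 and −0.84. Between compounds 2 were higher and 9 lower (3 and 9 adjusted over the list alone; adjusted p = 0.58).

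Interferon-stimulated genes rose in 4 and fell in 4 of 24 cases after DC-1-170 (adjusted p = 0.79), and rose in 9 and fell in 4 after DC-1-192 (median 0.12, mean −0.06, camera up, adjusted p = 0.61). IFIT5 fell from 12.3 ± 0.91 to 2.82 ± 0.37 CPM after DC-1-192 (−2.11) and IFIT3 by 2.38 on the log2 scale, while of the signalling factors STAT2 rose (0.61) and IRF9 fell (−0.86). Between compounds 3 were higher and 3 lower (median 0.07, mean −0.08, camera up, adjusted p = 0.79). Proteasome genes rose in 9 and fell in 1 of 31 cases after DC-1-170 (8 and 1 adjusted over the list alone; adjusted p = 0.11) and rose in 7 and fell in 6 after DC-1-192 (median 0.04, mean −0.02, camera up, adjusted p = 0.83), PSMD1, which overlaps HTR2B on the other strand, being the member that fell after DC-1-170 (−0.41). Between compounds 4 were lower and none higher (1 lower adjusted over the list alone; adjusted p = 0.12). Unfolded protein response genes rose in 5 and fell in 4 of 26 cases after DC-1-170 (4 and 4 adjusted over the list alone; adjusted p = 0.31), rose in 7 and fell in 6 after DC-1-192 (median 0.07, mean −0.01, camera up, adjusted p = 0.67), and were higher in 2 and lower in 4 between compounds (1 and 3 adjusted over the list alone; adjusted p = 0.72). The stress sensor ERN1 changed by −0.77 and −1.09 and the co-chaperone DNAJC3 by −0.43 and −0.62 after DC-1-170 and DC-1-192.

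Of 37 markers of other cell types 13 were abundant enough to test. After DC-1-170 1 rose and 2 fell (1 and none adjusted over the list alone; adjusted p = 0.79), after DC-1-192 5 rose and 3 fell (adjusted p = 0.63), and between compounds 1 was higher and 1 lower (none adjusted over the list alone; median 0.21, mean −0.03, camera up, adjusted p = 0.66). The monocyte marker CD14 stood at 0.24 ± 0.25, 1.14 ± 0.14 and 2.25 ± 0.51 CPM in untreated, DC-1-170 and DC-1-192 cells and lies 11.7 kb downstream of NDUFA2 on the same strand. The endothelial marker PECAM1 changed by −0.67 and −1.03. Unlike the groups above, ribosome biogenesis, heat shock and snoRNA host genes were called by camera for DC-1-192 and between compounds, but not for DC-1-170. Ribosome biogenesis genes after DC-1-170 rose in 4 and fell in 8 of 35 cases (median 0.06, mean −0.03, camera up, adjusted p = 0.91), heat shock genes rose in 1 and fell in 3 of 21 (none and 2 adjusted over the list alone; median 0.01, mean −0.01, camera down, adjusted p = 0.65), and snoRNA hosts rose in 8 and fell in 7 of 24 (median 0.03, mean −0.04, camera up, adjusted p = 0.97). DDX10, a ribosome biogenesis helicase, changed by −1.24 after DC-1-170 and −0.80 after DC-1-192.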
